A study of Mus musculus with 6 samples.

How the data were processed

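Droplet single-cell RNA was counted from the 5′ end of transcripts (10x Genomics immune profiling chemistry) in mouse material of the LL/2 model, a transplantable Lewis lung carcinoma line. Per the labels, each of the 6 libraries stands alone in its group. Library NS came from a tumour without treatment, DC from a tumour given dendritic cells, OCDC from a tumour given the OCDC vaccine, T from a tumour given transferred T cells, and NeOT from a tumour given OCDC together with neoantigen-reactive T cells. Library NooT is labelled as neoantigen-reactive T cells that had met OCDC, with tumour as its source, and the labels do not say whether it was a tumour or a cell product. The dendritic cells were grown from mouse bone marrow with GM-CSF and the vaccines were injected into the skin, per the submitters' protocols. The same protocols describe tumours under the skin and lung tumours seeded through a tail vein; which model each library came from is not given in the sources used here. The series text speaks of 5 groups, whereas 6 libraries are labelled.

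The deposited values are raw UMI counts (1 UMI stands for 1 captured RNA molecule) per gene and barcode. The authors made them with Cell Ranger 6.1.2 and the mouse genome build mm10, per the submitters' processing notes. Per the file headers, version 6.1.2 wrote library T and version 4.0.0 wrote the other 5 libraries. The gene table of library T lists 32285 identifiers and that of the other 5 lists 27998. Identifiers present in both tables (27040) were kept, and they hold between 99.5% and 99.8% of the UMIs of each library. The gene annotation release and the counting options are not given in the sources used here, and the labels word the kit version in several ways. The lowest barcode total was 2570 UMIs in library T against 500 to 810 in the other 5.

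Barcodes with at least 300 genes, at least 500 UMIs and at most 10% mitochondrial UMIs were kept. Barcodes over 10% made up 15.3% of library NS, 6.27% of DC, 4.44% of OCDC, 0.845% of T, 5.80% of NeOT and 0.135% of NooT. Doublets were called per library with Scrublet (as in scanpy 1.11.5, expected rate 0.06) and removed, which took 1.80, 3.66, 2.25, 0.669, 2.92 and 2.85% of the barcodes of NS, DC, OCDC, T, NeOT and NooT. Where the automatic threshold called under 0.5%, in T and NooT, the median threshold of the other 4 libraries, 0.259, was used instead. The retained cells of all 6 libraries were clustered together, without batch correction: 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1 and seed 7. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9 were used with it.

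Clusters took class names from 27 marker sets written down before the data were examined, together with the gene lists, the comparisons, the naming rule and the first set of alternatives. A marker counted as on in a cluster at 0.25 of its highest cluster level and at least 20 CPM (UMIs scaled to a class sum of 10⁶), and a name needed at least 3 markers on and a marker share of 0.5. A cluster with more markers of another class than of its own among its 10 leading genes stayed unnamed, which held for clusters 5 and 15 (3088 and 1343 cells with tumour markers) and for cluster 50 (36 cells with T markers), among others. Classes are written as T-like, tumour-like, and monocyte- and macrophage-like (shortened to macrophage-like), since names rest on markers alone. Of the other clusters, those in which the markers of the remaining lineages, at least 3 of them, lay at a median of 0.5 or more of their level in the whole library were called mixed and named no class. Clusters 22, 34, 39 and 62, unnamed by the rule of leading genes, reached that level as well and are not part of the mixed share (142, 115, 35 and 16 barcodes of T). That threshold was set after the clusters had been seen, so the mixed share is given per library. Of 63 clusters, 44 were named, 6 were mixed and 13 stayed unnamed.

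UMIs were summed per library and class, and levels are CPM of that sum over shared genes. Classes with at least 50 cells in both libraries were compared. Intervals of a level are exact Poisson, those of a ratio come from the exact binomial split of the counts of both libraries, and those of a share are exact (Clopper-Pearson), each at 95%. Square brackets hold these intervals, which cover counting error only. Because each group has 1 library, no test between groups could be run and no p-value is given; the differences include whatever sets 1 animal or 1 preparation apart from another. A ratio to a level of 0 was computed against a floor of 3 counts per library and is written as "at least". In the lists, such a bound was left out where it lay on the other side of 0 than the counts. The named genes of each comparison and class have at least 100 UMIs over both libraries and a ratio interval wholly beyond 1.5-fold, ranked by the bound nearest 1, with 5 taken in each direction. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, receptor, predicted, sex-linked and free-RNA genes were left out of that ranking. A gene counted as free RNA where its level in the class, in the library with the higher value, was under 0.1 of its highest level in another class of that library. Also named are the extreme members of the lists and the class markers, and other list members given as examples were chosen after their values were seen.

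A set of 15 lists (140 genes, of which Mx1 and Cxcl11 are not in the shared table) covered T cytotoxicity, T inhibitory receptors and exhaustion, T naive and memory, T activation and co-stimulation, regulatory T, proliferation, type I interferon, interferon-gamma, MHC class I and class II presentation, inflammatory and immunosuppressive macrophage, T-cell-attracting chemokines, hypoxia and glycolysis, and dissociation stress genes. The first 5 were read in T-like cells, MHC class II and hypoxia genes in tumour-like and macrophage-like cells, the macrophage lists in macrophage-like cells and the others in all 3 classes. Each list has the median log2 CPM ratio of its members with UMIs in both libraries, and the number of members at least 1.5-fold higher or lower. List brackets hold the middle 95% of 500 Poisson resamples. A percentile among 10000 random lists of like expression was taken as a description of these libraries. T-like cells were also split by UMIs of Cd8a or Cd8b1 and of Cd4, unthinned and thinned to 1000 UMIs per cell.

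The ratio method was tested on simulated data made from the depths of DC and NS, with 100 genes shifted at 2-fold and 100 at 4-fold per run. Counts were drawn as Poisson from the pooled level of each gene, the model that the intervals assume. The test therefore speaks to counting error alone and not to differences between cells or animals. At 2-fold it recovered 34 of 100 in T-like, 91 in tumour-like and 88 in macrophage-like cells, and at 4-fold 91, 100 and 100, with 0 unshifted genes called. Alternatives were a limit of 20% mitochondrial UMIs, at least 1000 genes per cell, doublets kept, Leiden resolution 2, a marker gate per cell in place of clusters, median-of-ratios scaling, genes shared by the compared pair alone, list members with at least 20 UMIs, thinned cells, and other rules for V genes. Chosen after the data were seen were the UMI minimum of library T (2570) in every library, mixed clusters left out of the denominator, list members passing the free-RNA rule, clusters of a class with at least 20 cells in both libraries weighted alike, tumour-like cells without clusters 38 and 41, clusters named by markers whatever genes lead them, and named genes without those 4-fold apart between library T and the other tumour libraries. Median-of-ratios scaling moved the median of all genes by 0.15 (log2) for T against NS in tumour-like cells and by under 0.1 in each other comparison. The paired receptor sequences were not used here.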

Results

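The study collected 5′ single-cell RNA counts from 6 libraries of the LL/2 mouse lung cancer model, 1 per group, around the question of whether a dendritic cell vaccine helps to ready neoantigen-reactive T cells for transfer. Untreated tumour (NS), dendritic cells (DC), OCDC vaccine (OCDC), transferred T cells (T) and OCDC with neoantigen-reactive T cells (NeOT) made up the 5 tumour libraries, and NooT held neoantigen-reactive T cells treated with OCDC. Total UMIs were 141049480 in NS, 207637803 in DC, 176353504 in OCDC, 122667401 in T, 174975269 in NeOT and 75959704 in NooT. In the same order, 7860, 11220, 10714, 10834, 9844 and 7877 cells were retained, with median UMIs of 13507, 14282, 13079, 5849.5, 13836 and 6842 per cell.

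T-like cells made up 2.01% [1.76 to 2.29] of the retained cells in DC and 1.95% [1.69 to 2.24] in NeOT. The share was 0.840% [0.650 to 1.07] in NS, 0.915% [0.743 to 1.11] in OCDC and 0.462% [0.343 to 0.608] in T. Among immune-like cells alone, T-like cells made up 2.61% in NS, 5.54% in DC, 3.01% in OCDC, 5.10% in T and 5.43% in NeOT. A marker gate per cell in place of clusters gave T-like shares of 1.53% in NS, 2.75% in DC, 1.68% in OCDC, 2.10% in T and 2.64% in NeOT. With the UMI minimum of library T applied to every library the share was 1.51% in DC and 1.49% in NeOT. Macrophage-like cells made up 27.4% of NS, 30.1% of DC, 25.5% of OCDC and 30.5% of NeOT, and tumour-like cells 45.4, 45.1, 53.2 and 50.3%. Neutrophil-like cells lay between 2.19% (NeOT) and 2.65% (OCDC) in these 4 libraries, and dendritic-cell-like cells between 0.985% (NeOT) and 1.32% (DC). Natural-killer-like cells, also killers, made up 0.254% [0.155 to 0.393] of NS, 0.187% of DC, 0.103% of OCDC, 0.0369% of T and 0.223% of NeOT. Unnamed clusters held 6.54% (T) to 16.6% (NS) of cells in the 5 tumour libraries. Many of these cells had tumour markers but other leading genes, and counting them by their markers gave tumour-like shares of 60.2% in NS, 58.6% in DC, 64.0% in OCDC, 24.4% in T and 59.3% in NeOT.

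Library T differed in makeup, since mixed clusters held 62.0% of its cells against 3.17% in NS, 1.16% in DC, 1.88% in OCDC and 0.538% in NeOT. NooT had 0, but its main clusters 9, 12, 14, 16 and 23 had enough marker RNA of 2 lineages only. The mixed rule asks for at least 3, so those clusters could not be called mixed. Tumour-like cells made up 20.9% of T and macrophage-like cells 7.86%. Among these tumour-like cells, 28 of the 38 cells of cluster 38, led by macrophage genes (Lyz1, Cbr2 and Lyz2), were found, and 25 of the 26 of cluster 41, led by macrophage genes (Ccl8 and Marco) beside tumour markers (Prl2c2 and Prl2c3); with both left out, the tumour-like share of T was 20.4%. With the mixed clusters left out, these shares were 55.1% and 20.7%, and the T-like share of T was 1.21%. NooT was 98.5% [98.3 to 98.8] T-like, with 63 B-like, 34 dendritic-cell-like and 8 macrophage-like cells. Tumour-like cells numbered 0 of 7877 in NooT (a share of 0 [0 to 0.0468%]).

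**Figure D1:**
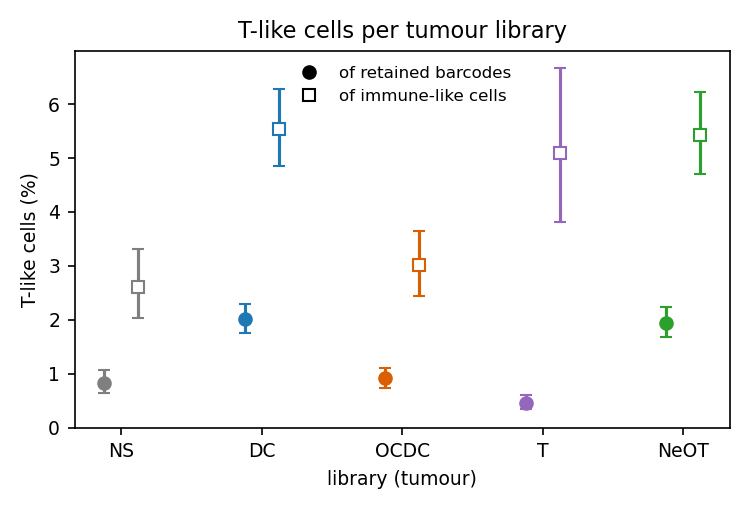
T-like cells as a percent of all retained cells and of immune-like cells in the 5 tumour libraries, with exact 95% binomial intervals. DC (2.01%) and NeOT (1.95%) lie above NS (0.840%), OCDC (0.915%) and T (0.462%) among retained cells, whereas T (5.10%) joins DC and NeOT among immune-like cells.

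CD8 T cells kill and CD4 T cells help or restrain. Cells with Cd8a or Cd8b1 UMIs and no Cd4 made up 19.7% [10.9 to 31.3] of T-like cells in NS, 20.8% [15.7 to 26.7] in DC, 14.3% [8.04 to 22.8] in OCDC, 18.0% [8.58 to 31.4] in T and 16.1% [11.2 to 22.1] in NeOT, and the intervals of these 5 overlap. NooT had 10.1% [9.44 to 10.8], or 4.97% when thinned to 1000 UMIs per cell. Thinned in the same way, the CD8 shares were 13.6% in NS, 20.1% in DC, 13.4% in OCDC, 10.0% in T and 16.3% in NeOT. Cells with Cd4 and neither Cd8 gene made up 33.3, 38.5, 35.7, 50.0, 42.2 and 44.3% of T-like cells in NS, DC, OCDC, T, NeOT and NooT. Thinned, the Cd4 shares were 12.1, 20.1, 15.5, 22.0, 22.3 and 10.8%. Tumour-like cells, which should lack these genes, had Cd8a or Cd8b1 UMIs in 0.0280 (NS) to 0.573% (T) and Cd4 UMIs in 0.0280 (NS) to 0.441% (T). For these shares the other gene was not asked to be absent. Median UMIs in T-like cells were 3515, 2906, 2808, 5083, 2779 and 6910, and those of tumour-like cells ran from 17331 (T) to 24490 (DC).

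T-like cells of the tumour libraries lay mostly in cluster 19 (led by Cd4, Cxcr6 and Il7r), 44 (Cpm and Hspa1b), 45 (Ctla4 and Foxp3), 47 (Gzma and Cd8b1) and 48 (Dapl1 and Ly6c2). Cluster 19 held 16.7% of them in NS, 21.2% in DC, 29.6% in OCDC, 30.0% in T and 43.8% in NeOT. For cluster 45, whose leading genes include Foxp3, the shares were 27.3%, 14.2%, 15.3%, 16.0% and 10.4% in the same order. DC also had 24 of its 226 T-like cells in cluster 51, which Gzmb, Ifng and Gzmf lead. NooT had other clusters: 9 (Tnfrsf9, Il2ra and Foxp3), 12 (Lef1 and Ccr7), 14 (Il2, Il13 and Il17a), 16 (Il22 and Csf2) and 23 (Gbp2 and Ifit3).

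DC against NS asked how a tumour given dendritic cells differed from an untreated one. T-like cells of DC held more RNA of killing genes than those of NS. Gzmb (ENSMUSG00000015437), a granzyme of killer lymphocytes, stood at 1009 against 505 CPM (2.00-fold [1.66 to 2.42] higher), the granule gene Nkg7 was 1.86-fold [1.56 to 2.24] higher and Ifng, the gene of interferon-gamma, 1.93-fold [1.30 to 2.96] higher. The T cytotoxicity list had 9 of 12 members at least 1.5-fold higher and 2 lower (Gzma and Gzmc), with a median log2 ratio of 0.95 [0.77 to 1.20], or 2.04 with a marker gate per cell. Perforin (Prf1) was 7.37-fold [3.07 to 23.1] higher with 70.7% of its UMIs in 5 cells, and Gzmf (ENSMUSG00000015441) was at least 23.5-fold higher with all its UMIs in 2 cells. Checkpoint genes were higher as well, with 6 of 10 members of the inhibitory list (median 0.75), among them Ctla4 (2.71-fold [2.01 to 3.74]), Lag3 (2.98-fold [1.68 to 5.76]) and Pdcd1 (1.68-fold [1.24 to 2.32]). Activation and co-stimulation genes had 6 of 10 members higher (median 0.70), such as Cd27 (3.18-fold [1.71 to 6.55]) and Icos (1.93-fold [1.37 to 2.80]). Proliferation genes had 10 of 12 higher (median 1.75), including Top2a (3.36-fold [1.55 to 8.64]) and Birc5 (4.92-fold [1.83 to 18.6]), while Mki67 was about level (57.2 against 54.9 CPM). Naive and memory genes (-0.16) and regulatory T genes (-0.08) had medians near 0. The chemokines Ccl3 (41.8-fold [16.2 to 154]) and Ccl4 (3.41-fold [2.75 to 4.27]) and the signalling gene Rgs16 (20.3-fold [9.78 to 50.8]) led the higher genes, with 86.1, 56.7 and 44.0% of their UMIs in 5 cells. Ly6c2 (2.20-fold [1.75 to 2.75], 71.6% in 5 cells), Tmem176b (2.36-fold [1.69 to 3.29]) and Lars2 (2.01-fold [1.66 to 2.45]) were lower. The dissociation stress list was also higher in these cells, with 7 of 10 members and a median of 0.78.

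Macrophage-like cells of DC carried more RNA of MHC class II genes and of some interferon-gamma response genes. Cxcl9 (ENSMUSG00000029417), an interferon-induced chemokine that attracts T cells, stood at 96.2 against 24.6 CPM (3.91-fold [3.55 to 4.31] higher), and Gbp2 (ENSMUSG00000028270), a guanylate-binding protein gene of the same response, was 1.70-fold [1.55 to 1.87] higher. Interferon-gamma response genes had 4 of 10 members higher and 0 lower (median 0.51 [0.45 to 0.60]). MHC class II genes, which present antigen to CD4 T cells, had 6 of 7 higher (median 0.68 [0.63 to 0.74]), with H2-Aa at 1675 against 1015 CPM and Cd74 1.55-fold [1.54 to 1.57] higher. With the clusters of the class weighted alike this median was 0.31. Immunosuppressive macrophage genes had 4 of 10 lower (median -0.36): Arg1, an arginine-consuming enzyme (1.58-fold [1.54 to 1.62]), Chil3 (1.94-fold [1.82 to 2.06]), Cd163 (1.58-fold [1.34 to 1.85]) and Retnla (43.6-fold [14.4 to 215], 3 against 90 UMIs, those of NS in 4 cells). Type I interferon genes had 2 of 10 higher (median 0.28), namely Ifit2 (1.74-fold [1.52 to 1.99]) and Ifit3 (1.52-fold [1.34 to 1.72]). Dnase1l3 (2.92-fold [2.11 to 4.12]), Gbp8 (2.73-fold [1.97 to 3.84]), Fam26f (2.41-fold [2.01 to 2.90]) and the lipase Lpl (2.41-fold [1.99 to 2.93]) were further higher genes. Lower ones were the eosinophil chemokine Ccl24 (2.94-fold [2.54 to 3.42]), Fam71a (2.72-fold [1.83 to 4.10]), Htra4 (2.37-fold [1.56 to 3.65]) and the platelet gene Ppbp (1.92-fold [1.72 to 2.13], 52.3% of UMIs in 5 cells). Median log2 ratios of the other lists were 0.25 for MHC class I, 0.24 for inflammatory macrophage, 0.29 for chemokine, -0.26 for hypoxia, 0.03 for proliferation and 0.10 for stress genes.

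In tumour-like cells of DC, Mta1, a chromatin remodelling gene, was 3.28-fold [3.15 to 3.42] higher over 3927 cells, Mdga1 2.28-fold [1.67 to 3.15] higher and the heat shock gene Hspb1 1.64-fold [1.61 to 1.67] higher. Csf3 (3.14-fold [2.28 to 4.41] higher) and the mast cell gene Mcpt4 (100.2-fold [17.7 to 3984] higher) lay in 15 and 4 cells. The muscle genes Tnnc2 (84.6-fold [32.6 to 313]), Myl1 (44.2-fold [19.9 to 122]), Acta1 (15.8-fold [13.1 to 19.2]), Ckm (6.69-fold [4.37 to 10.6]) and Tnni2 (5.05-fold [3.83 to 6.74]) were lower, with over 80% of their NS UMIs in 5 cells. Acta1, Myl1 and Ckm turned to higher under other filters, with log2 ratios of 1.39, 0.64 and 1.06 at a limit of 20% mitochondrial UMIs. List medians were 0.21 for proliferation, -0.08 for type I interferon, 0.56 for interferon-gamma, 0.23 for MHC class I, -0.88 for MHC class II, 0.21 for chemokine, -0.13 for hypoxia and -0.01 for stress genes. In T-like cells the corresponding medians were 0.18 for type I interferon, 0.39 for interferon-gamma, 0.44 for MHC class I and 0.93 for chemokine genes. In tumour-like cells, here and in the other comparisons, each MHC class II and chemokine gene and most interferon genes lay under 0.1 of their level in another class of the library, where genes counted as free RNA.

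OCDC against NS asked how a tumour given the OCDC vaccine differed from an untreated one. Its T-like cells had higher proliferation genes, with 9 of 12 members (median 0.99 [0.49 to 1.83]), such as Birc5 (4.54-fold [1.53 to 18.2]) and Rrm2 (2.94-fold [1.04 to 10.2]), although the marker gate per cell gave a median of -0.10. The NS sum held 4 UMIs of Birc5 and 5 of Rrm2. Cytotoxicity genes split into 3 higher and 3 lower of 11 (median 0.28, or 0.13 with zeros at their bound), with Gzmb 1.68-fold [1.35 to 2.10] higher, Gzmk 4.84-fold [1.84 to 16.0] higher and Gzma 1.81-fold [1.30 to 2.55] lower. Inhibitory receptor genes had 1 higher and 3 lower of 10 (median -0.56), with Ctla4 1.87-fold [1.32 to 2.69] higher and Lag3 at 27.1 against 50.9 CPM. Naive and memory (-0.09), activation (-0.02) and regulatory T genes (-0.21) had medians near 0, with Icos 2.00-fold [1.35 to 3.01] higher. The RNA-binding genes Zfp36 (2.24-fold [1.80 to 2.81]) and Zfp36l2 (1.86-fold [1.51 to 2.30]) were higher, Zfp36 reversing to a log2 ratio of -0.05 with the marker gate. Cxcl10 (3.47-fold [2.39 to 5.15]) and Ccl4 (2.42-fold [1.67 to 3.55]) were lower, with 83.3 and 88.0% of their UMIs in 5 cells. Stress genes had a median of 0.39, type I interferon genes -0.20, interferon-gamma genes -0.01, MHC class I genes -0.05 and chemokine genes -0.40.

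Macrophage-like cells of OCDC had lower chemokine RNA than those of NS. T-cell-attracting chemokines had 4 of 6 members lower (median -0.82 [-0.88 to -0.72]): Cxcl10 (1.82-fold [1.71 to 1.94]), Ccl4 (1.80-fold [1.76 to 1.84]), Cxcl9 (1.73-fold [1.497 to 1.99]) and Ccl5 (2.02-fold [1.76 to 2.33]). Interferon-gamma response genes had 3 of 10 lower and 0 higher (median -0.35 [-0.49 to -0.28]), with Gbp2 1.62-fold [1.43 to 1.84] lower. In the type I interferon list 2 of 10 were lower (median -0.37), and the stress median was -0.31. The monocyte chemokine Ccl8 was 3.26-fold [3.05 to 3.49] lower, Ccl24 1.84-fold [1.60 to 2.12] lower and Retnla 6.68-fold [3.84 to 12.4] lower from 4 NS cells. MHC class II genes had a median of -0.32, or -0.10 with clusters weighted alike. Higher were Vsig4, a complement receptor gene of resident macrophages (2.55-fold [2.03 to 3.22]), Dnase1l3 (2.58-fold [1.83 to 3.69]) and Stac2 (2.24-fold [1.74 to 2.90]), together with the scavenger receptor Marco (9.31-fold [5.37 to 17.5]) and Cd209f (5.58-fold [3.16 to 10.6]), which lay in 19 and 9 cells. Immunosuppressive genes had 3 of 10 lower (median -0.06), with Arg1 at 806 against 708 CPM. Inflammatory (-0.21), MHC class I (-0.13), hypoxia (0.09) and proliferation genes (-0.04) had medians near 0.

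Tumour-like cells of OCDC had 6 of 10 type I interferon genes lower (median -0.61), but the 2 members passing the free-RNA rule gave -0.07. Mta1 was 1.62-fold [1.55 to 1.69] higher and the mast cell gene Cma1 5.88-fold [3.14 to 12.2] higher in 17 cells. Acta1 (45.2-fold [33.0 to 63.5]), Myl1 (126-fold [34.3 to 1046]), Tnnc2 (107-fold [36.1 to 522]), Ckm (11.4-fold [6.64 to 21.0]) and Tnni2 (3.73-fold [2.89 to 4.84]) were lower, and Ckm and Tnni2 turned to higher at a limit of 20% mitochondrial UMIs (log2 ratios 0.24 and 0.57). Dissociation stress genes had 2 of 10 lower (median -0.49), including Atf3 (1.91-fold [1.86 to 1.95]) and Egr1 (1.93-fold [1.87 to 2.00]). Further medians were -0.45 for interferon-gamma, -0.13 for MHC class I, -1.03 for MHC class II, -0.86 for chemokine, 0.17 for hypoxia and 0.12 for proliferation genes.

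OCDC against DC set both vaccines side by side. T-like cells of OCDC had less RNA of killing and checkpoint genes than those of DC. Cytotoxicity genes had 8 of 12 members lower and 0 higher (median -0.75, or -0.97 with zeros at their bound), with Ifng at 57.6 against 219 CPM (3.81-fold [2.31 to 6.68]), Prf1 (3.88-fold [2.09 to 7.98]) and Cst7 (2.59-fold [1.73 to 3.99]) among the lower and Gzmb at 849.8 against 1009 CPM. This median was -1.56 with the marker gate per cell. In clusters 19 and 44 alone, weighted alike, it was 0.17; Cd4 is among the leading genes of both, and the CD8 clusters 47 and 51, led by Gzma and Gzmb, held under 20 cells in OCDC and are not part of that value. Inhibitory genes had 6 of 10 lower (median -0.90), with Lag3 5.60-fold [2.76 to 13.3], Nr4a2 5.88-fold [3.01 to 13.1] and Pdcd1 2.49-fold [1.77 to 3.58] lower. Activation genes had 4 of 10 lower (median -0.43) and proliferation genes 5 of 12 (median -0.43, or 0.89 in clusters 19 and 44 alone). Ccl3 (10.7-fold [6.73 to 18.3]), Ccl4 (8.25-fold [6.101 to 11.4]), Rgs16 (7.84-fold [5.07 to 12.8]) and Gzmf (at least 27.2-fold, 2 DC cells) were the other lower genes. Anxa1, an anti-inflammatory annexin gene (2.91-fold [2.15 to 3.93]), the actin-binding gene Cald1 (3.33-fold [2.25 to 4.96]) and the histone genes Hist1h3c (3.89-fold [2.66 to 5.72]), Hist1h3f (3.24-fold [2.16 to 4.88]) and Hist1h2ab (2.84-fold [2.11 to 3.84]) were higher. Other medians were 0.05 for naive and memory, -0.22, or -0.36 with zeros at their bound, for regulatory T, -0.44 for type I interferon, -0.41 for interferon-gamma, -0.26 for MHC class I, -2.48 for chemokine and -0.42 for stress genes.

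Macrophage-like cells of OCDC had less interferon-gamma response, chemokine and MHC class II RNA than those of DC. Cxcl9 stood at 14.3 against 96.2 CPM (6.75-fold [6.01 to 7.60] lower), Gbp2 was 2.76-fold [2.48 to 3.08] lower and Cxcl10 2.64-fold [2.498 to 2.79] lower. Interferon-gamma response genes had 8 of 10 members lower and 0 higher (median -0.89 [-1.02 to -0.79], percentile 0 among random lists of these libraries). MHC class II genes had 7 of 7 lower (median -1.05 [-1.07 to -0.96]), with H2-Aa at 811 against 1675 CPM, and weighting the clusters alike gave -0.39. Type I interferon genes had 5 of 10 lower (median -0.68) and the chemokines 5 of 6 (median -1.13), and the stress list had 3 of 10 lower with them (median -0.43). Ifnb1, the gene of interferon-beta, was 28.0-fold [10.7 to 104] lower, with 4 against 146 UMIs and the DC UMIs in 28 cells. Ccl8 was 5.50-fold [5.17 to 5.86] lower. Immunosuppressive genes had 3 higher and 1 lower of 10 (median 0.10), with Arg1 1.80-fold [1.76 to 1.84] and Chil3 2.31-fold [2.18 to 2.45] higher. The glutathione gene Gsta4 (3.87-fold [2.51 to 6.12]), the neuropeptide gene Npy (3.83-fold [2.504 to 6.00]) and Cdc42bpa (3.74-fold [2.44 to 5.87]) were higher, and so were Marco (4.20-fold [2.99 to 6.01], 87.6% in 5 cells) and Cd209f (3.55-fold [2.34 to 5.50], 9 cells). Inflammatory genes had a median of -0.41, MHC class I genes -0.41, hypoxia genes 0.29 and proliferation genes -0.03.

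In tumour-like cells OCDC had lower heat shock and early response genes than DC, Dnajb1 by 1.74-fold [1.72 to 1.77] and Atf3 by 1.89-fold [1.85 to 1.93], and 6 of 10 stress genes were lower (median -0.64). Mta1 was 2.03-fold [1.97 to 2.09] lower, as were Acta1 (2.87-fold [1.99 to 4.21]) and Mcpt4 (3.5997-fold [2.53 to 5.24], 4 DC cells), the last turning to a log2 ratio of 4.86 at Leiden resolution 2. The troponin gene Tnnt2 (2.06-fold [1.77 to 2.40]), Frzb (2.17-fold [1.55 to 3.09]), Cck (2.02-fold [1.51 to 2.73]) and the proliferin gene Prl2c3 (2.34-fold [2.03 to 2.71], 52.5% in 5 cells) were higher. Bnip3, a hypoxia-induced gene, was 1.51-fold [1.47 to 1.56] higher (hypoxia median 0.19). The type I interferon median was -0.58, or -0.09 among the 2 members passing the free-RNA rule and 0.13 with clusters weighted alike. Other medians were -0.999 for interferon-gamma, -0.37 for MHC class I, -0.16 for MHC class II, 0.19, or -0.04 with zeros at their bound, for chemokine and -0.09 for proliferation genes.

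**Figure D2:**
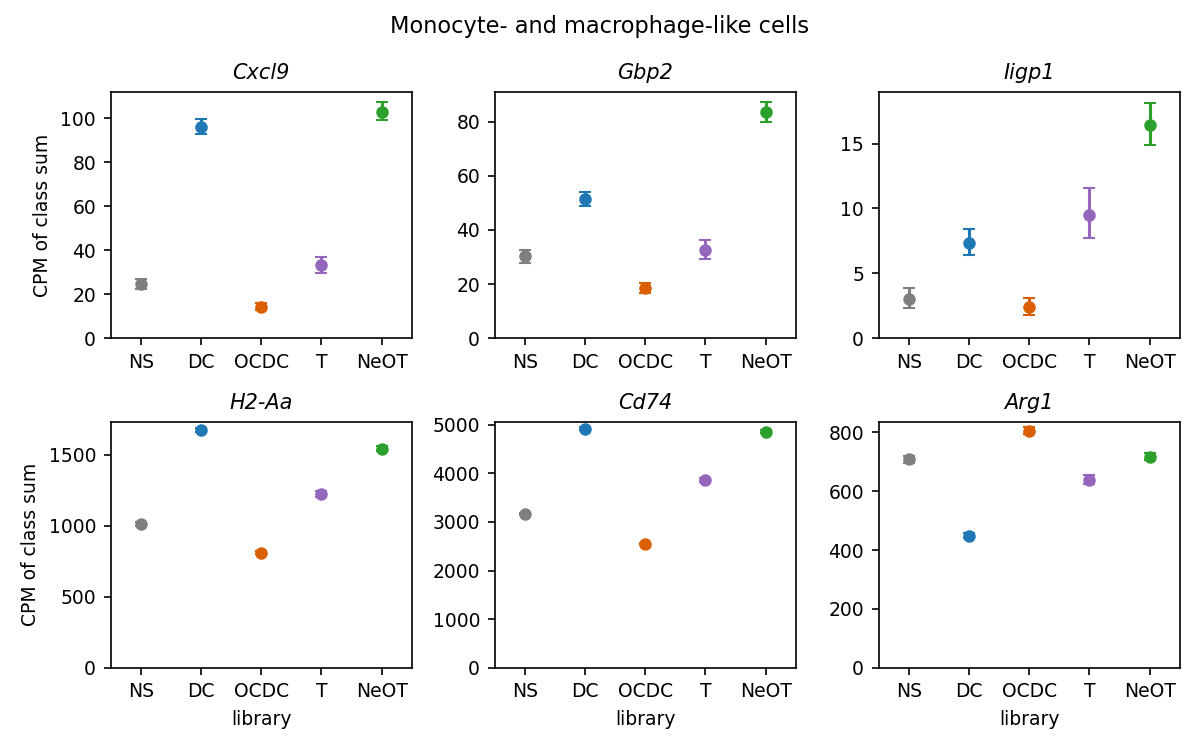
Levels (CPM, with exact 95% Poisson intervals) of Cxcl9, Gbp2, Iigp1, H2-Aa, Cd74 and Arg1 in macrophage-like cells of the 5 tumour libraries. Cxcl9 stands at 96.2 CPM in DC and 103 CPM in NeOT against 14.3 CPM in OCDC, 24.6 CPM in NS and 33.3 CPM in T.

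T against NS asked how a tumour given transferred T cells differed from an untreated one. Here single genes from outside the lists had the largest ratios. Srp54a (ENSMUSG00000073079) was at least 994-fold higher in tumour-like cells of T, Cfap43 (ENSMUSG00000044948) 901-fold [161 to 35594] lower and Fam89b 77.1-fold [63.4 to 94.8] higher. In macrophage-like cells Apoc2, an apolipoprotein gene, led the higher genes (1578-fold [282 to 62394] higher, 806 against 1 UMI), and Srp54a, Fam89b and Cfap43 were named there too. In all, 23 genes were higher and 13 lower by 4-fold or more in T than in each of the other 4 tumour libraries in both classes, of 9110 with enough UMIs. Among them were Srp54a, Fam89b, Tomm6 and Mrpl53 (higher) and Cfap43, Ptp4a1, Lrrc24, Hspa14, Ece2 and Tonsl (lower). Ccnb1ip1, Platr25 and Tmem265 (higher in tumour-like cells by at least 129-fold, 470.4-fold [83.8 to 18642] and at least 62.2-fold) and Apoc2 were not among them and still led with them left out. Among the genes then named in macrophage-like cells of T were the nucleoside kinase gene Nme1 5.22-fold [4.88 to 5.59] higher, Chd9 4.21-fold [3.86 to 4.59] higher and the microglia-type gene Tmem119 2.30-fold [2.01 to 2.64] lower. The rule that left genes out asks for enough UMIs and 4-fold in both classes, so it cannot take out a gene low in either. In NeOT, Apoc2, Ccnb1ip1 and Tmem265 had 0 UMIs and Platr25 had 2. For these, Nme1 and Chd9, another gene reference in T cannot be told apart from a difference of the sample. Median log2 ratios in tumour-like cells stand against a scaling shift of 0.15.

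T-like cells of T, 50 in number, had Ctla4 3.00-fold [2.15 to 4.25] higher (65.8% of UMIs in 5 cells), with S100a4 (2.43-fold [2.00 to 2.98]), Rgs1 (2.51-fold [2.01 to 3.15]) and the naive-cell factor Tcf7 (2.71-fold [1.501 to 5.15]) also higher. Tomm6 was 17.9-fold [7.97 to 49.9] and the ribosomal RNA gene AY036118 2.12-fold [1.84 to 2.44] higher. Gzma (ENSMUSG00000023132) was 6.35-fold [3.66 to 11.8] lower, its NS UMIs lying in 6 cells, and Gzmb was 2.14-fold [1.57 to 2.96] lower at 236 against 505 CPM. Cytotoxicity genes had 4 higher and 4 lower of 11 (median -0.02, or -0.95 at Leiden resolution 2). The interferon-induced genes Isg15 (4.36-fold [2.97 to 6.58]) and Bst2 (2.71-fold [1.81 to 4.15]) were lower, but with the marker gate per cell their log2 ratios were 0.68 and 0.06. The co-stimulatory receptors Tnfrsf4 (2.38-fold [1.81 to 3.16]) and Tnfrsf9 (2.23-fold [1.73 to 2.89]) were lower too, and the regulatory T list had 4 of 7 lower (median -0.81). Proliferation genes had 9 of 12 higher (median 1.45), such as Top2a (3.52-fold [1.48 to 9.65], with 7 UMIs in NS). Medians were -0.34 for inhibitory, 0.24 for naive and memory, 0.03 for activation, -0.62 for type I interferon (1.19 with the marker gate), 0.28 for interferon-gamma, -0.06 for MHC class I, 0.81 for chemokine and 0.40 for stress genes. Of the 50 T-like cells, 47 had UMIs of a receptor beta V gene, spread over 19 genes with Trbv3 leading in 7 cells (14.9% [6.204 to 28.3], Simpson index 0.0810). Such UMIs occurred in 1.54% of tumour-like, 0.587% of macrophage-like and 2.49% of mixed barcodes of T.

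Macrophage-like cells of T had 4 of 10 type I interferon genes higher (median 0.27), with Ifit2 (2.49-fold [2.14 to 2.89]) and Ifit3 (2.33-fold [2.03 to 2.69]) leading, whereas the marker gate gave a median of -0.09. Interferon-gamma response genes had 1 of 10 higher, Iigp1 (3.14-fold [2.26 to 4.40]), and a median of 0.34, or 0.01 with the marker gate. Cd80, a co-stimulatory ligand gene, was 1.88-fold [1.57 to 2.25] higher and Chil3 2.03-fold [1.86 to 2.23] lower. MHC class II genes had a median of 0.27, which turned to -0.05 with the marker gate. The other medians were -0.05 for MHC class I, -0.06 for inflammatory, -0.15 for immunosuppressive, 0.15 for chemokine, -0.15 for hypoxia, -0.02 for proliferation and -0.17 for stress genes. Mki67 was 1.66-fold [1.60 to 1.71] higher in tumour-like cells (proliferation median 0.18). Their MHC class II (0.99) and chemokine medians (0.96) turned to -0.23 and -0.69 with clusters weighted alike, cluster 7 holding 40.2% of tumour-like cells in T and 17.9% in NS. Type I interferon (0.03, or -0.50 with clusters weighted alike), interferon-gamma (0.36), MHC class I (-0.08), hypoxia (-0.12) and stress medians (-0.12) complete the tumour-like lists.

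NeOT against OCDC asked what adding neoantigen-reactive T cells to the vaccine went with. T-like cells of NeOT had Ifng at 169 against 57.6 CPM (2.93-fold [1.74 to 5.22] higher, 57.3% of UMIs in 5 cells), the T cell chemokine Ccl5 1.90-fold [1.74 to 2.06] higher and Nkg7 1.67-fold [1.41 to 1.98] higher. Cytotoxicity genes had 5 of 11 members higher and 0 lower (median 0.61, or 1.42 with the marker gate per cell), while Gzmb stood at 758 against 849.8 CPM. Chemokine genes had 5 of 7 higher (median 1.95), with Ccl4 (3.96-fold [2.89 to 5.54]) and Cxcl10 (3.76-fold [2.67 to 5.41]) having 79.2 and 46.4% of UMIs in 5 cells. Regulatory T genes had 3 of 7 lower (median -0.67, or 0.29 with the marker gate), with Il2ra, the interleukin-2 receptor alpha gene, 2.07-fold [1.34 to 3.18] lower and Foxp3, the regulatory T cell factor, at 40.9 against 60.9 CPM. Gadd45b was 2.61-fold [1.57 to 4.58] higher, Tmem176b 4.01-fold [2.61 to 6.26] lower and Fos 1.74-fold [1.52 to 1.98] lower, the last turning to a log2 ratio of 0.03 with the marker gate. Medians were 0.17 for inhibitory, -0.25 for naive and memory, 0.18 for activation, 0.31 for proliferation, -0.24 for type I interferon, 0.11 for interferon-gamma, 0.11 for MHC class I and -0.48 for stress genes.

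Macrophage-like cells of NeOT had more interferon-gamma response RNA than those of OCDC. Cxcl9 was 7.23-fold [6.43 to 8.15] higher, the interferon-induced GTPase gene Iigp1 6.86-fold [5.15 to 9.29], Gbp2 4.49-fold [4.04 to 5.00] and Ccl8 4.09-fold [3.83 to 4.36] higher. Interferon-gamma response genes had 7 of 10 members higher and 0 lower (median 0.76 [0.64 to 0.86], percentile 100 among random lists). MHC class II genes had 6 of 7 higher (median 0.93 [0.89 to 0.94]), Cd74 by 1.91-fold [1.89 to 1.93], and 0.49 with the clusters weighted alike. Inflammatory genes had 3 of 9 higher (median 0.48), among them Tnf (1.72-fold [1.59 to 1.86]). Type I interferon genes had 2 of 10 lower (median -0.16), namely Irf7 (1.51-fold [1.41 to 1.61]) and Usp18 (1.66-fold [1.38 to 2.00]). Retnla was 83.2-fold [50.2 to 149] higher, but 8 cells held its UMIs and the log2 ratio was -1.39 with the marker gate. Lower genes were the Langerhans cell gene Cd207 (2.72-fold [1.83 to 4.12]), Fndc7 (2.81-fold [1.80 to 4.51]), the cold-induced gene Cirbp (1.91-fold [1.71 to 2.12]), Erdr1 (2.08-fold [1.70 to 2.55]) and Ace (2.03-fold [1.67 to 2.48]). Immunosuppressive (0.00), MHC class I (0.19), chemokine (0.47), hypoxia (-0.22), proliferation (-0.11) and stress genes (0.09) had smaller medians.

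Tumour-like cells of NeOT had the amino acid stress genes Chac1 (1.72-fold [1.61 to 1.85]) and Trib3 (1.71-fold [1.61 to 1.81]) higher than OCDC, with Rbp4 (1.60-fold [1.54 to 1.67]), Gap43 (1.91-fold [1.61 to 2.28]) and Acta1 (3.20-fold [2.23 to 4.68]). The hypoxia genes Ankrd37 (2.04-fold [1.91 to 2.18]) and Bnip3 (1.51-fold [1.46 to 1.55]) were lower, and 3 of 12 hypoxia genes in all (median -0.12). Bhlhe40 (1.87-fold [1.78 to 1.96]), Cck (4.54-fold [3.04 to 6.98]), Frzb (2.68-fold [1.85 to 3.95]) and Tnnt2 (1.97-fold [1.69 to 2.30]) were lower too. The type I interferon median of -0.82 was -0.03 among the 2 members passing the free-RNA rule, and the interferon-gamma median of 0.45 was -0.06 among its 2. Others were 0.12 for MHC class I, 0.10 for MHC class II, -0.34, or -0.21 with zeros at their bound, for chemokine, 0.07 for proliferation and -0.27 for stress genes.

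NeOT against NS asked how the combined treatment differed from no treatment. T-like cells of NeOT had 8 of 11 cytotoxicity genes higher and 1 lower (median 0.87 [0.57 to 0.99], or 1.81 with the marker gate), with Ccl5 (1.90-fold [1.74 to 2.08]), Nkg7 (1.83-fold [1.52 to 2.21]) and Gzmb (1.5004-fold [1.23 to 1.84]) as examples. Proliferation genes had 10 of 12 higher (median 1.49), with Top2a (2.93-fold [1.32 to 7.66]), Mcm5 (6.13-fold [1.97 to 30.9]) and the chromatin gene Hmgb2 (1.96-fold [1.54 to 2.53]). The NS sum held 7 UMIs of Top2a and 3 of Mcm5. Foxp3 stood at 40.9 against 106 CPM (2.58-fold [1.44 to 4.64] lower), alongside the smaller share of cluster 45 in NeOT, and Tnfrsf4 (1.91-fold [1.55 to 2.33]) and Tnfrsf9 (1.91-fold [1.58 to 2.31]) were lower, although Tnfrsf4 (0.09) and the regulatory T median (-0.37 to 0.57) turned with the marker gate. The phosphatase gene Dusp2 (2.47-fold [1.88 to 3.29]) and Lpxn (2.83-fold [1.72 to 4.94]) were higher, and Tmem176b (4.64-fold [3.03 to 7.24]) and the stress gene Atf3 (3.10-fold [2.09 to 4.64]) lower. Activation genes had 4 of 10 higher (median 0.34) and chemokines 6 of 7 (median 0.74). The other medians were 0.02 for inhibitory, -0.41 for naive and memory (0.60 with the marker gate), -0.55 for type I interferon, 0.35 for interferon-gamma, 0.10 for MHC class I and -0.20 for stress genes.

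Macrophage-like cells of NeOT had Cxcl9 4.19-fold [3.80 to 4.62] higher, Iigp1 5.46-fold [4.16 to 7.27] higher and Gbp2 2.77-fold [2.53 to 3.04] higher than NS. Interferon-gamma response genes had 4 of 10 higher (median 0.46 [0.34 to 0.60]) and MHC class II genes 4 of 7 (median 0.60 [0.41 to 0.62]), with H2-Aa at 1543 against 1015 CPM. Type I interferon genes had 4 of 10 lower (median -0.43 [-0.52 to -0.39]), the transcription factor gene Irf7 by 1.88-fold [1.76 to 2.01]. The monocyte chemokine Ccl12 (2.58-fold [2.503 to 2.67]), the cholesterol hydroxylase Ch25h (1.97-fold [1.78 to 2.17]), Tmem119 (1.92-fold [1.75 to 2.11]) and Erdr1 (2.16-fold [1.76 to 2.66]) were lower. Cd80 was 1.89-fold [1.63 to 2.21] higher and Marco 18.2-fold [10.7 to 33.7] higher in 43 cells, while Retnla (12.5-fold [10.1 to 15.6] higher) and Cd209f (8.69-fold [5.01 to 16.3] higher) lay in 8 cells each. Retnla turned to a log2 ratio of -3.90 at 1000 genes per cell or more. Inflammatory (0.15), immunosuppressive (-0.07), MHC class I (0.05), chemokine (-0.25), hypoxia (-0.21), proliferation (-0.18) and stress genes (-0.18) had smaller medians. In tumour-like cells Banp (1.85-fold [1.70 to 2.01]), the endocytic receptor Lrp2 (2.05-fold [1.70 to 2.497]), Grb14 (1.78-fold [1.55 to 2.05]), Rsrp1 (1.63-fold [1.59 to 1.68]) and Mta1 (1.61-fold [1.54 to 1.69]) were higher. Stress genes had 7 of 10 lower there (median -0.76), with Egr1 2.86-fold [2.76 to 2.97] and Fos 1.91-fold [1.88 to 1.93] lower. Acta1 (14.1-fold [11.8 to 17.1]), Tnnc2 (17.8-fold [11.0 to 30.6]), Myl1 (15.7-fold [9.42 to 28.1]), Ckm (11.4-fold [6.65 to 21.0]) and Tnni2 (3.64-fold [2.84 to 4.72]) were lower, and Acta1 turned to a log2 ratio of 0.84 at the limit of 20% mitochondrial UMIs. The type I interferon median of -1.38 was -0.10 among the 2 members passing the free-RNA rule. Tumour-like medians were 0.11 for interferon-gamma, 0.05 for MHC class I, -0.89 for MHC class II, -0.82 for chemokine, -0.09 for hypoxia and 0.21 for proliferation genes.

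**Figure D3:**
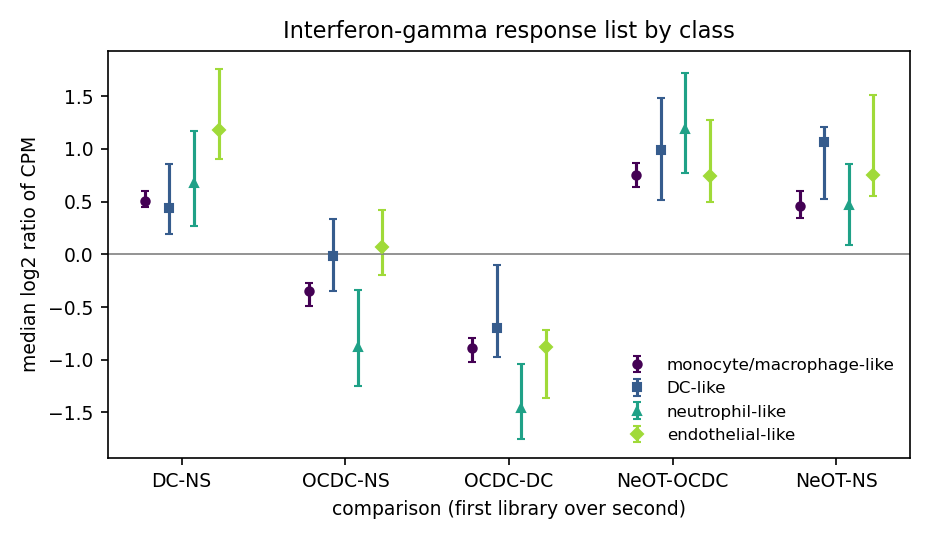
Median log2 ratio of the interferon-gamma response list for the 5 comparisons without T and NooT in macrophage-like, dendritic-cell-like, neutrophil-like and endothelial-like cells, with the middle 95% of 500 Poisson resamples as bars. For OCDC against DC the medians were -0.89, -0.70, -1.45 and -0.87 in that order, and for NeOT against OCDC 0.76, 0.99, 1.19 and 0.74.

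NeOT against T asked how the combined treatment differed from T cell transfer alone. T-like cells of NeOT had 7 of 11 cytotoxicity genes higher and 0 lower (median 0.99 [0.35 to 1.20], or 1.53 at Leiden resolution 2), with Gzmb at 758 against 236 CPM (3.22-fold [2.46 to 4.27] higher, 60.9% of UMIs in 5 cells) and Ccl5 1.99-fold [1.82 to 2.18] higher. The interferon-induced genes Ifit1 (3.73-fold [2.44 to 5.94]) and Isg15 (2.90-fold [2.01 to 4.32]) and the chemokine Ccl4 (2.82-fold [2.12 to 3.83], 79.2% in 5 cells) were higher. Naive and memory genes had 5 of 9 lower (median -0.59), with Tcf7 2.73-fold [1.73 to 4.33] and Klf2 2.33-fold [2.01 to 2.71] lower, whereas the marker gate gave a median of 0.08. Foxp3 was 3.78-fold [2.24 to 6.49] lower. S100a4 (3.37-fold [2.86 to 3.99]), Rgs2 (3.78-fold [2.77 to 5.20], 86.2% in 5 cells) and Il17a (4.07-fold [2.81 to 5.96], 2 cells) were lower as well, and stress genes had 7 of 10 lower (median -0.76). Medians were -0.02 for inhibitory, 0.04 for activation, 0.30 for regulatory T, 0.39 for proliferation, 0.33 for type I interferon, 0.14 for interferon-gamma, 0.23 for MHC class I and 1.17 for chemokine genes.

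**Figure D4:**
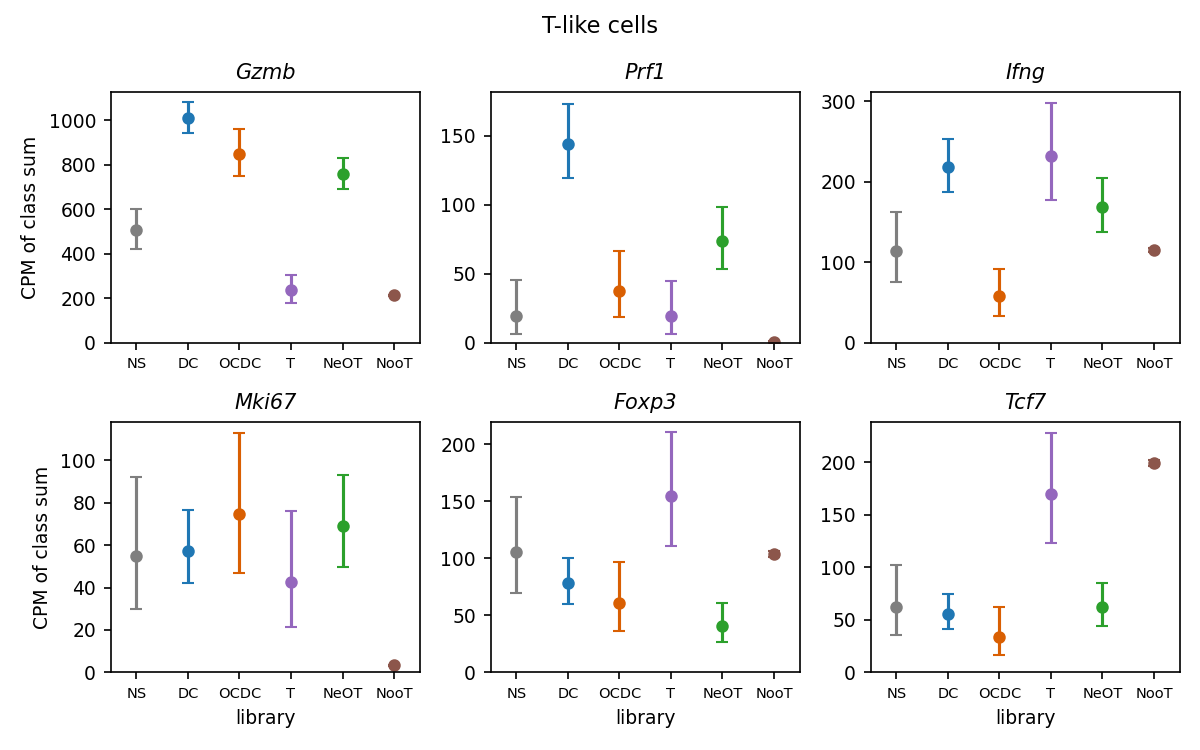
Levels (CPM, with exact 95% Poisson intervals) of Gzmb, Prf1, Ifng, Mki67, Foxp3 and Tcf7 in T-like cells of the 6 libraries. Gzmb stands at 1009 CPM in DC, 849.8 in OCDC, 758 in NeOT, 236 in T and 212 in NooT.

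Macrophage-like cells of NeOT and T differed in interferon genes in both directions. Of 10 type I interferon genes 8 were lower in NeOT (median -1.01 [-1.09 to -0.93]), with Ifit3 (3.51-fold [3.02 to 4.09]), Ifit2 (3.05-fold [2.62 to 3.56]) and Usp18 (2.46-fold [2.01 to 3.02]), while Cxcl9 (3.10-fold [2.77 to 3.48]), Gbp2 (2.56-fold [2.28 to 2.88]) and Iigp1 (1.74-fold [1.39 to 2.19]) were higher (interferon-gamma median 0.22). MHC class II genes had a median of 0.25, or 0.60 with the marker gate. Genes at least 4-fold apart in T led again, such as Ece2, Tonsl and Sco2. Without them, Apoc2 led the lower genes (at least 623-fold, 0 against 806 UMIs), then Atrip (14.2-fold [8.04 to 27.1]) and Slc8a1 (7.20-fold [5.13 to 10.3]). For these and Trf, another gene reference in T cannot be told apart from a difference of the sample. Marco (43.4-fold [14.7 to 212]) and the lysozyme gene Lyz1 (3.28-fold [3.10 to 3.48]) were higher and the iron carrier gene Trf (5.16-fold [4.61 to 5.79]) lower, and Retnla (95.5-fold [43.7 to 261] higher) again lay in 8 cells and turned to a log2 ratio of -1.05 at 1000 genes per cell or more. Further medians were 0.11 for MHC class I, 0.01 for inflammatory, 0.08 for immunosuppressive, -0.19 for chemokine, 0.03 for hypoxia, -0.09 for proliferation and -0.04 for stress genes. In tumour-like cells, Cfap43, Ptp4a1, Lrrc24, Hspa14 and Fam220a were higher in NeOT and Srp54a, Ccnb1ip1, Platr25, Tmem265 and Fam89b lower, all by 26.3-fold or more. Fos (1.89-fold [1.86 to 1.91]) and Egr1 (2.29-fold [2.19 to 2.39]) were among 6 of 10 lower stress genes (median -0.71). Tumour-like medians were -1.27 for type I interferon (0.01 for the 1 member passing the free-RNA rule), -1.88 for MHC class II (0.16 with clusters weighted alike), -1.51 for chemokine (0.19 in the same way), -0.23 for interferon-gamma, 0.14 for MHC class I, 0.09 for hypoxia and -0.00 for proliferation genes.

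NooT was compared with NS and NeOT in T-like cells alone, to describe neoantigen-reactive T cells treated with OCDC beside T cells in tumours. NooT cells carried cytokine RNA that tumour T-like cells nearly lacked. Il2 (ENSMUSG00000027720), the T cell growth factor, was at least 226-fold higher than in NS and lay in 1247 cells, with the type 2 cytokine Il13 (at least 79.7-fold), Il22 (at least 76.0-fold) and Il17f (at least 50.1-fold). Il2 and Il13 lead cluster 14 and Il22 leads cluster 16, so these genes also define NooT clusters. Ccr7 (ENSMUSG00000037944), a lymph node homing receptor, stood at 3906 against 43.1 CPM (90.6-fold [50.6 to 182] higher) over 6665 cells. Naive and memory genes had 5 of 9 higher and 2 lower (median 1.63 [0.83 to 1.84]), with Tcf7 (3.18-fold [1.96 to 5.57]) and Lef1 (3.21-fold [2.06 to 5.34]) higher and Il7r (6.27-fold [5.05 to 7.70]) lower. Cytotoxicity genes had 10 of 12 lower (median -3.56, but 0.33 with the marker gate per cell): Gzma by 377-fold [273 to 521], Ccl5 by 22.4-fold [20.6 to 24.3] and Gzmb by 2.38-fold [1.99 to 2.83], while Ifng stood at 115 against 114 CPM and Gzmf had 14 against 0 UMIs. The NS UMIs of Gzma lay in 6 cells. Type I interferon genes had 8 of 10 higher (median 2.02 [1.52 to 2.31]), such as Irf7 (9.00-fold [5.45 to 16.1]), and interferon-gamma genes 8 of 10 (median 1.69 [1.46 to 2.33]), such as Gbp2 (18.4-fold [8.93 to 45.8]). The regulatory T list had 4 of 7 higher (median 0.99), with Il2ra (8.93-fold [6.00 to 13.9]) and Tnfrsf4 (3.96-fold [3.41 to 4.61]) higher and Foxp3 level (104 against 106 CPM). Proliferation genes had 9 of 12 lower (median -2.84), Mki67 by 16.9-fold [9.11 to 29.0]. The heat shock genes Hspa1a (617-fold [491 to 780.3]) and Hspa1b (462-fold [388 to 551]), Nedd4 (86.2-fold [60.8 to 120.2]) and S100a6 (44.0-fold [40.5 to 47.8]) were lower. Other medians were -1.18 for inhibitory (1.62 with the marker gate), 0.20, or 0.32 with zeros at their bound, for activation, 0.74 for MHC class I, -1.81 for chemokine and -1.66 for stress genes.

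Against NeOT, NooT cells had Il13 (at least 191-fold), Il17f (at least 119.7-fold), Il2 (270.0-fold [124 to 736], 189951 against 6 UMIs), Il22 (545-fold [97.9 to 21545], 63955 against 1 UMI) and Ccr7 (91.7-fold [62.6 to 140.4]) higher. The activating receptor Klrk1 (125-fold [86.4 to 182]), Hspa1a (533-fold [433 to 661]), Hspa1b (333-fold [284 to 392]) and the histone genes Hist1h3c (1098-fold [589 to 2268]) and Hist1h2ab (367-fold [253 to 544]) were lower, as was Ccl5 (42.6-fold [40.7 to 44.5]). Proliferation genes had 12 of 12 lower (median -4.45 [-4.66 to -4.00]) and cytotoxicity genes 9 of 12 (median -3.68, or -1.80 with the marker gate), whereas Gzmc stood at 14.0 against 8.19 CPM and Gzmf had 14 against 0 UMIs. Regulatory T genes had 5 of 7 higher (median 1.34), naive and memory genes 5 of 9 (median 1.68), type I interferon genes 7 of 10 (median 2.63) and interferon-gamma genes 8 of 10 (median 1.54). Inhibitory (-0.83, or 0.73 with the marker gate), activation (-0.35, or 1.34 with it), MHC class I (0.72), chemokine (-3.60) and stress medians (-1.32) complete the lists. The median depth of T-like cells was 6910 UMIs in NooT against 3515 in NS and 2779 in NeOT, and whether NooT cells came from a tumour or a culture is not given in the sources used here. NooT also lacked tumour-like cells, and histone genes and Nedd4 are among the leading genes of the largest mixed cluster. For genes lower in NooT, proliferation genes among them, free tumour RNA in T-like barcodes of NS and NeOT cannot be told apart from a T cell difference.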

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

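The tests of cell pairs per droplet, of the gene reference and of T cell transfer shared with NeOT were chosen only after the results were seen.

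Receptor constant genes have identifiers in the gene table of library T and not in the shared table, so the comparisons do not use them, and they were looked at here because they gave a signal in data outside those comparisons. Trbc2 (ENSMUSG00000076498), the gene of a T cell receptor constant region, had UMIs in 33 of 50 T-like cells of T (66.0% [51.2 to 78.8]), against 1.10% of tumour-like, 0.235% of macrophage-like and 0.982% of mixed barcodes. Trac (ENSMUSG00000076928) had UMIs in 30.0% and Trbc1 in 26.0% of the T-like cells. Median UMIs were 5083 in T-like and 17331 in tumour-like cells of T, so the deeper class had the lower share.

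Most barcodes of library T lay in mixed clusters, where genes of T, macrophage and tumour lineages occur together. A cell population of its own after T cell transfer, confined to the largest mixed cluster, was argued against. Only 1 gene, the secretory granule gene Chga (3.43 against at most 0.579 CPM), lay at least 4-fold above every other class and unnamed cluster of T. Those unnamed clusters include 22, 34 and 39, which reached the mixed level as well, so genes shared with them could not count. For a population spread over them too, the test cannot decide. Droplets with 2 or more cells were argued against as well, because the largest mixed cluster had a median of 4224 UMIs and the named cells of T 12536, a ratio of 0.337. Free RNA in droplets without a cell stays open as a candidate explanation. For 8 of 8 named classes the class-specific genes stood in that cluster at 0.703 to 1.06 times their level in the summed named cells. That cluster was called mixed for such levels of lineage markers, so this outcome was largely set in advance and lends no support of its own. The T-like share of T depends on how mixed clusters are read, at 0.462% with and 1.21% without them in the denominator. The deposited table of T holds exactly 11000 barcodes; whether its barcode calling was forced to that number is not given in the sources used here, so what the mixed share says about the tumour is open.

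Genes such as Srp54a, Fam89b, Cfap43 and Ptp4a1 stood at least 4-fold apart between library T and NS in tumour-like cells. T cell transfer itself, which NeOT shares, was argued against as the cause: the median log2 ratio of NeOT to NS over these genes was -0.073 in the direction of T, where T to NS gave 3.17. Another gene reference in library T may stand behind them and cannot be told apart from a difference of the sample, because 76.2% of the genes (32 of 42) were as far apart in both classes and against each of the other 4 tumour libraries, under the 80% set for a clear answer. The demand for 100 UMIs in every pair was added once the value had been seen. The same 32 genes made up 47.1% of all 68, a count that takes each gene without those UMIs as not apart. The share without that demand was not computed. The 47.1% therefore cannot be set against the 50% that would have counted against another gene reference.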

How the results depend on the processing

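For 489 reported values, 4781 values under alternatives were computed, of which 89 turned the sign of a value whose interval left out 0 and 126 that of a list median whose interval held 0. The UMI minimum of library T in every library, mixed clusters left out, list members passing the free-RNA rule, clusters weighted alike, clusters 38 and 41 left out and clusters named by markers alone were chosen only after the data had been seen. Values are log2 ratios unless a percent sign follows, and for each value given here the cause was not tested.

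Interferon-gamma medians in macrophage-like cells kept their direction under every alternative run, at -0.97 to -0.81 for OCDC to DC, 0.69 to 0.87 for NeOT to OCDC, 0.47 to 0.57 for DC to NS, 0.40 to 0.56 for NeOT to NS, -0.40 to -0.33 for OCDC to NS, 0.18 to 0.31 for NeOT to T and 0.01 to 0.40 for T to NS. MHC class II medians there kept theirs in the comparisons without T, at -1.07 to -0.39 for OCDC to DC, 0.49 to 0.95 for NeOT to OCDC, 0.31 to 0.71 for DC to NS, 0.43 to 0.62 for NeOT to NS and -0.37 to -0.10 for OCDC to NS. T cytotoxicity medians kept theirs for DC to NS (0.88 to 2.04), NeOT to NS (0.63 to 1.81), NeOT to OCDC (0.36 to 1.42), NeOT to T (0.55 to 1.53), OCDC to NS (0.07 to 0.47) and NooT to NeOT (-4.30 to -1.80), while that of T to NS, near 0 as reported, ran from -0.95 to 0.57. Clusters weighted alike had a T-like value for OCDC to DC and NeOT to OCDC alone, and there for clusters 19 and 44 alone, since no other cluster held at least 20 T-like cells in both libraries.

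The marker gate per cell gave T-like shares of 1.53% in NS, 2.75% in DC, 1.68% in OCDC, 2.10% in T, 2.64% in NeOT and 97.2% in NooT. CD8-gate shares were 10.8% in NS, 15.6% in DC and 4.39% in T, and CD4-gate shares 16.7% in NS, 29.9% in DC, 19.4% in OCDC, 14.0% in T and 33.1% in NeOT. T cytotoxicity medians became 2.04 for DC to NS, 1.81 for NeOT to NS, 1.42 for NeOT to OCDC, 1.38 for NeOT to T, -1.56 for OCDC to DC, -1.80 for NooT to NeOT and, with the other sign, 0.33 for NooT to NS. MHC class II medians in macrophage-like cells became 0.62 (NeOT to NS), 0.60 (NeOT to T), -0.28 (OCDC to NS) and, reversed, -0.051 (T to NS), and the interferon-gamma median of T to NS there 0.011. Type I interferon medians in tumour-like cells became -1.68 for NeOT to T, -0.47 for OCDC to NS and 0.37 for T to NS.

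Further lists reversed under the marker gate. In T-like cells these were inhibitory genes of NooT to NS (1.62) and to NeOT (0.73), activation genes of NooT to NeOT (1.34), naive and memory genes of NeOT to NS (0.60) and to T (0.076), regulatory T genes of NeOT to NS (0.57) and to OCDC (0.29), proliferation genes of OCDC to NS (-0.096), type I interferon genes of T to NS (1.19) and stress genes of NeOT to OCDC (0.047), OCDC to NS (-0.38) and T to NS (-0.23). In macrophage-like cells they were chemokines of NeOT to T (0.26) and T to NS (-0.33), stress genes of NeOT to T (0.055) and type I interferon genes of T to NS (-0.085), and in tumour-like cells chemokines of NeOT to OCDC (0.030) and hypoxia genes of NeOT to T (-0.062). Single genes that reversed with it were Bst2 (0.064) and Isg15 (0.68) for T to NS, Cxcl10 (0.26) and Zfp36 (-0.054) for OCDC to NS, Fos (0.033) for NeOT to OCDC and Tnfrsf4 (0.094) for NeOT to NS, all in T-like cells. Others were Acta1 for DC (0.58) and NeOT (0.59), Myl1 for NeOT (0.40) and Tnni2 for NeOT (0.16) and OCDC (0.16) to NS, Mcpt4 for OCDC to DC (3.17), and Retnla for NeOT to NS (-4.07), to OCDC (-1.39) and to T (-0.77).

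Leiden resolution 2 gave T-like shares of 0.757% in T and 96.5% in NooT, cytotoxicity medians of 1.53 (NeOT to T) and -0.95 (T to NS), and MHC class II medians in macrophage-like cells of 0.20 (NeOT to T), -0.28 (OCDC to NS) and 0.34 (T to NS). It reversed activation genes of NooT to NeOT (0.092), naive and memory genes of NeOT to T (0.17) and proliferation genes of NeOT to T in macrophage-like cells (0.017). Genes it reversed against NS in tumour-like cells were Acta1 in DC (1.28) and NeOT (0.84), Ckm in DC (0.68), Myl1 in DC (0.63) and NeOT (0.31) and Tnni2 in NeOT (0.14) and OCDC (0.32). Mcpt4 of OCDC to DC (4.86) and Retnla of NeOT to NS (-4.12), OCDC (-0.10) and T (-1.28) reversed too.

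At least 1000 genes per cell gave a T-like share of 99.2% in NooT, cytotoxicity medians of -2.76 (NooT to NS) and -4.10 (NooT to NeOT) and MHC class II medians in macrophage-like cells of 0.16 (NeOT to T) and 0.35 (T to NS). Reversed were chemokines of NeOT to OCDC in tumour-like cells (0.094), proliferation genes of NeOT to T in macrophage-like cells (0.016), Retnla of NeOT to NS (-3.90) and T (-1.05), and against NS Acta1 (1.28), Ckm (1.15) and Myl1 (0.13) in DC, Ckm (0.24) and Tnni2 (0.56) in OCDC and Tnni2 in NeOT (0.27). A limit of 20% mitochondrial UMIs moved the MHC class II medians of DC to NS (0.62) and T to NS (0.29) and reversed, against NS, Acta1 (1.39), Ckm (1.06) and Myl1 (0.64) in DC, Ckm (0.24) and Tnni2 (0.57) in OCDC and Acta1 (0.84), Myl1 (0.31) and Tnni2 (0.16) in NeOT. Doublets kept gave MHC class II medians of 0.62 (NeOT to NS), 0.94 (NeOT to OCDC), 0.18 (NeOT to T) and 0.36 (T to NS) in macrophage-like cells, a cytotoxicity median of -2.72 (NooT to NS) and, reversed, 0.0083 for chemokines of NeOT to OCDC in tumour-like cells.

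Thinning to 1000 UMIs gave CD4-gate shares of 12.1% in NS, 20.1% in DC, 15.5% in OCDC, 22.0% in T, 22.3% in NeOT and 10.8% in NooT and a CD8-gate share of 4.97% in NooT, which its own construction lowers. Median-of-ratios scaling gave MHC class II medians in macrophage-like cells of 0.95 (NeOT to OCDC), -1.07 (OCDC to DC), -0.37 (OCDC to NS) and 0.20 (T to NS) and reversed MHC class I genes of NeOT to NS in tumour-like cells (-0.0050).

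The UMI minimum of library T in every library gave T-like shares of 1.51% in DC, 1.49% in NeOT and 99.3% in NooT, a CD4-gate share of 45.5% in DC, a cytotoxicity median of -4.30 (NooT to NeOT) and an MHC class II median of 0.29 (T to NS, macrophage-like). It reversed Acta1 (1.27), Ckm (0.83) and Myl1 (0.66) of DC, Myl1 (0.40) and Tnni2 (0.014) of NeOT and Tnni2 of OCDC (0.42) to NS, and Retnla of NeOT to NS (-3.91) and T (-0.72). Mixed clusters left out gave a T-like share of 1.21% in T.

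Clusters weighted alike gave MHC class II medians in macrophage-like cells of 0.31 (DC to NS), 0.49 (NeOT to OCDC), -0.39 (OCDC to DC), -0.10 (OCDC to NS) and 0.11 (T to NS). Type I interferon in tumour-like cells became -0.20 (DC to NS), -0.72 (NeOT to T) and -0.50 (T to NS). In T-like cells, clusters 19 and 44 alone gave cytotoxicity medians of 1.42 (NeOT to OCDC) and 0.17 (OCDC to DC, with the other sign) and a proliferation median of 0.89 (OCDC to DC, with the other sign); the CD8 clusters 47 and 51 are left out of these values, so they do not stand for the class. Reversed in tumour-like cells were type I interferon of OCDC to DC (0.13), MHC class II of NeOT to NS (0.0053), NeOT to T (0.16) and T to NS (-0.23), chemokines of NeOT to T (0.19) and T to NS (-0.69), interferon-gamma of NeOT to T (0.091) and proliferation of NeOT to OCDC (-0.010).

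List members passing the free-RNA rule gave type I interferon medians in tumour-like cells of -0.10 (NeOT to NS), -0.029 (NeOT to OCDC), -0.091 (OCDC to DC), -0.074 (OCDC to NS), -0.21 (T to NS) and, reversed, 0.011 (NeOT to T), from 1 or 2 members each. Interferon-gamma genes of NeOT to OCDC had 0.87 in macrophage-like and, reversed, -0.063 in tumour-like cells. MHC class II medians in macrophage-like cells became 0.84 (NeOT to OCDC), -0.25 (OCDC to NS) and 0.22 (T to NS), and cytotoxicity medians -2.61 (NooT to NS) and -2.96 (NooT to NeOT).

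Clusters named by markers whatever genes lead them gave type I interferon medians in tumour-like cells of 0.084 (DC to NS), -1.05 (NeOT to NS), -1.09 (NeOT to T), -0.42 (OCDC to DC) and -0.25 (OCDC to NS), and moved 30 of 225 list medians, 13 of 215 named genes and 6 of 36 class shares. Clusters 38 and 41 left out of the tumour-like class moved 1 of 56 list medians there, 0 of 66 named genes and 0 of 6 shares.

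Of the list medians, 109 of 225 moved beyond their intervals under the marker gate without a reversal of the first kind, 73 of 148 with clusters weighted alike, 57 of 225 at Leiden resolution 2, 50 of 225 under median-of-ratios scaling, 40 of 225 at 1000 genes, 39 of 170 at the UMI minimum of T, 32 of 211 by the free-RNA rule, 29 of 203 with doublets kept, 24 of 225 at 20% mitochondrial UMIs and 2 of 225 among members with at least 20 UMIs. Of the named genes, 73 of 209 moved beyond their intervals under the marker gate, 29 at Leiden resolution 2, 24 at 1000 genes, 22 at the UMI minimum of T, 16 at 20% mitochondrial UMIs, 6 with doublets kept and 5 under scaling. Genes shared by the compared pair alone moved 0 of 167 list medians and 0 of 155 named genes, library T left out. Class shares moved in 20 of 36 cases under the marker gate and 9 at 20% mitochondrial UMIs. The share of the leading Trbv gene in T was 17.1% among cells with at least 2 UMIs of it and 25% in the CD8 gate alone, where Trbv1 led with 2 of 8 cells.

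With doublets kept no cluster was named neutrophil-like, so that class had no value. V genes could be counted in library T alone, and list levels within the CD8 gate were not computed because no pair of libraries had at least 50 such cells in both. Depth limits the T-like class above all: its UMIs summed to 255233 in NS, 295370 in OCDC and 258705 in T. A 2-fold difference was recovered for 34 of 100 simulated genes at the depths of DC (803654 UMIs) and NS. The shallower pairs, OCDC and T against NS, were not simulated.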

Other observations

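Of the tests below, those of cluster makeup and of handling stress were chosen only after the results were seen. The dendritic-cell-like, neutrophil-like and endothelial-like classes, on which the test across the whole tumour rests, were also chosen after the main results were seen.

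Dendritic-cell-like, neutrophil-like and endothelial-like cells, read in no comparison above, numbered 115, 284 and 67 in OCDC and 148, 294 and 90 in DC. Dendritic-cell-like cells had type I interferon genes higher than NS in DC (6 of 9 members, median log2 ratio 1.29), in OCDC (6 of 9, 1.19) and in NeOT (6 of 10, 0.80), whereas macrophage-like cells had medians of 0.28, -0.31 and -0.52, in each class over the members passing the free-RNA rule. Stress medians of dendritic-cell-like cells against NS were -0.16 in DC, -0.22 in OCDC and -0.62 in NeOT, the last with 6 of 10 members lower. Interferon-gamma response genes of OCDC against DC had medians of -0.70 in dendritic-cell-like, -1.45, or -1.46 with zeros at their bound, in neutrophil-like and -0.87 in endothelial-like cells. NeOT against OCDC gave 0.99, 1.19 and 0.74 in the same order. Stress genes of NeOT against OCDC moved as well. Their medians were -0.36 [-0.54 to -0.25] in dendritic-cell-like cells (0 higher and 4 lower of 10) and 0.18 in neutrophil-like cells (2 higher and 0 lower). In endothelial-like cells the median was -0.44 [-0.49 to -0.29] (0 higher and 3 lower). MHC class I genes of endothelial-like cells had 6 of 9 members lower in OCDC than in DC (median -0.68) and 6 of 9 higher in NeOT than in OCDC (0.76).

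Interferon-gamma response genes such as Cxcl9 and Gbp2 stood lower in macrophage-like cells of OCDC than in those of DC and NeOT. Another makeup of clusters within the class was argued against as the whole cause, since weighting the clusters alike left the OCDC to DC median at -0.81, although the MHC class II median went from -1.05 to -0.39. For NeOT against OCDC in macrophage-like cells the stress median was 0.090, which counted against handling stress, but a median near 0 without its members' spread cannot decide. Handling stress stays open for OCDC against DC in macrophage-like cells, where the stress median was -0.43. The same holds in neutrophil-like cells for OCDC against DC (-0.46) and for NeOT against OCDC (0.18 [0.09 to 0.32], 2 of 10 higher). In endothelial-like cells, whose interferon-gamma median was lower too, handling stress was argued against for OCDC against DC, with a stress median of 0.067 [-0.031 to 0.15] and 0 of 10 members lower. Dendritic-cell-like cells had 1 higher and 3 lower of 10 members (stress median -0.06 [-0.19 to 0.04]), so it stays open there. A difference across the whole tumour rather than in 1 class is a candidate explanation, because the highest of the OCDC to DC medians of dendritic-cell-like, neutrophil-like and endothelial-like cells, over members passing the free-RNA rule, was -0.70. The vaccines and the added T cells stay open as well, as does whatever else set these 3 libraries apart, and neither was tested.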
